A study of Mus musculus with 4 samples.

How the data were processed

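RNA extracted with Trizol from sorted mouse spleen cells had been labelled with biotin and hybridised to a 1-colour Affymetrix whole-genome mouse array, per the labels' protocols. The 4 arrays hold CD4+ Foxp3+ cells without Nrp1 (2 arrays) and with Nrp1 (2 arrays). The values deposited by the authors are probe set signal intensities on a linear scale, made with MAS5 per the submitters' processing notes. The version of that software, its settings and its detection calls are not given in the sources used here. From the values, the authors had scaled each array to a fixed mean: after trimming 2% of the probe sets at each end, the mean was 500.003 on both arrays numbered replicate 1 and 150.001 on both arrays numbered replicate 2. The median deposited intensity was 78.2 and 76.7 on the arrays numbered 1 and 20.2 and 21.3 on those numbered 2.

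The group of each array was taken from its title, which is the label unique to it. The array titled Nrp1-negative replicate 1 has a source name and a cell type that read as positive, and an age range of 4 to 8 weeks where the other 3 arrays have 4 to 6 weeks. The title was kept because it completes 2 groups of 2, and alternatives left this array out or counted it as Nrp1-positive. Nothing in the labels says that the 2 arrays of a group came from separate mice or sorts. How much of the spread between arrays is technical is therefore not known, and no p-value can be read as a spread between mice. Xist, a noncoding RNA of female cells, had intensities of 79.4 and 14682 on Nrp1-positive replicates 1 and 2, and 4100 on Nrp1-negative replicate 1. These values argue against one shared pool of mice behind the 2 Nrp1-positive arrays, or behind the 2 arrays of replicate 1. The number of arrays limits the precision of every value.

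The replicate number marked a technical batch in the files themselves. Besides the scaling target, the 12 probe sets for the spiked poly-A control transcripts had high intensities on both arrays of replicate 1 and almost none on both of replicate 2. The ratio of the 3-prime to the 5-prime Gapdh control probe set was 1.74 and 1.54 in batch 1 and 0.763 and 0.711 in batch 2, Nrp1-negative array first. The same ratio for Actb was 1.76 and 1.59 in batch 1 and 1.26 and 1.18 in batch 2. Across the 10200 genes tested, Pearson correlations between arrays were 0.979 and 0.985 within a batch and 0.941 and 0.956 within a group, and genes are not independent replicates. The first principal component separated the batches and held 71.8% of the variance. No pair of arrays shared identical values. Each batch holds 1 array of each group, so values are given within each batch and with the batch as a block beside the test without it.

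Because the trimmed means differed 3.33-fold, above the limit of 1.2 set before the data were examined, all arrays were scaled to one trimmed mean and quantile normalised. Values were then analysed as log2(intensity + 18.3), where the pseudocount is 0.25 of the mean array median, so a fold change understates that of dim genes. Of 45101 probe sets, 64 were controls, 34945 were listed with 1 gene, 932 with several and 9160 were unnamed here. Gene names came from the platform annotation, and 0 symbols changed when updated through the RefSeq gene table. Probe sets at or above percentile 50 of mean level were kept, which left 22519, and a gene was represented by its passing probe set with the highest mean. This gave 10200 genes. Of the genes on the fixed lists, 26 had no probe set listed with that gene alone.

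Groups were compared with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment at 0.05, as Nrp1-positive minus Nrp1-negative. The test without a block was fixed before the data were examined, and the test with the replicate number as a block was fixed then as an alternative. With the block, 1 residual degree of freedom per gene joined 17.7 from the variance prior. Its standard errors and p-values thus rest mostly on the variance of genes of similar level. The 20 gene lists, with 315 genes, were also fixed then: Treg core, higher and lower in thymus-derived Treg, naive and central T cell, effector Treg, homing receptors, T helper lineage, follicular helper, TCR-induced and immediate early, proliferation, type I interferon response, TGF-beta pathway, semaphorin with plexin and VEGF, glycolysis, heat shock and stress, and markers of B cells, plasmacytoid dendritic cells, myeloid cells with conventional dendritic cells, CD8 T with NK cells, and erythroid cells. Lists were tested with camera at an inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 20 lists. Drawings were made with matplotlib 3.10.9.

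Genes were named by a rule fixed before the data were examined. It takes, among genes past the threshold whose groups do not overlap, the 15 with the largest difference in each direction. A direction with fewer than 10 is filled to 10 by lowest p among genes with a log2 difference of at least 1 and no overlap, named as not past the threshold. It adds the sort markers, up to 6 members of each list past the threshold over all genes or over the list alone, and the 2 brightest members of each list of other cell types. The rule was also applied to the test with the batch as a block, and 35 genes were named by its first parts, 15 of them in both tests. Genes that are named otherwise are given as chosen after their values were seen.

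Both tests were run on simulated data with 10200 genes, 200 of them changed, in 20 runs for this comparison. The simulated batch effect, variances and variance prior came from the fit with the block and the trend, and noise was independent between genes. The rates below hold for such data only. Without the block, 0% of genes changed by a log2 of 1 and 5.39% of those changed by 2 were recovered. With the block, 36.0%, 81.5% and 96.8% of genes changed by 0.5, 1 and 2 were recovered, and 11.0% of calls were false, above the 5% the adjustment aims at. Without the mean-variance trend, the test with the block recovered 7.12% at 1 and 88.8% at 2, with 3.27% of calls false. Camera called a list of 20 genes shifted by 0.4 in 20 of 20 runs and an unchanged list in 0 of 20. Genes were not correlated in these runs, so they do not show how camera does on correlated genes. Alternatives covered the pseudocount, the filter, the normalisation, the choice of probe set, the variance prior, the block and each array left out. Fits with an array left out had no block and kept 1 batch only in a group, so the batch difference enters their group difference. The effect of the alternatives is given in the closing section.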

Results

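Regulatory T cells were compared by whether they carried Nrp1 (neuropilin-1), a receptor for semaphorins and vascular endothelial growth factor. The cells came from spleens of Balb/c mice with a fluorescent reporter for Foxp3, the transcription factor that defines regulatory T cells, and were sorted as CD4+ Foxp3+ with or without Nrp1. Each group had 2 arrays, 4 in all, and the arrays numbered 1 and those numbered 2 formed separate technical batches with 1 array of each group in both. Intensities are normalised signals, and differences are Nrp1-positive minus Nrp1-negative on the log2 scale.

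The sorted marker was recovered in the RNA of every array. Nrp1 had a mean intensity of 8558 ± 734 (SD, n = 2) in Nrp1-positive and 781 ± 625 in Nrp1-negative cells, a log2 difference of 3.68, or 12.9-fold. The difference was 4.67 in batch 1 and 2.70 in batch 2, and over all 4 Nrp1 probe sets it ranged from 3.48 to 5.80 in batch 1 and from 2.67 to 2.89 in batch 2. The array titled Nrp1-negative replicate 1, whose other labels read as positive, had an Nrp1 intensity of 339 against 9077 for Nrp1-positive replicate 1. The Nrp1 difference was 2.79 without Nrp1-negative replicate 1 and 4.58 without Nrp1-negative replicate 2. It was 1.26 with Nrp1-negative replicate 1 counted as Nrp1-positive. Ikzf2, which encodes the Ikaros-family transcription factor Helios, was also higher in Nrp1-positive cells in both batches, by 0.95 and 0.75. With limma and the batch as a block, Nrp1 had a standard error of 0.25 and an adjusted p = 1.31e-07, and Ikzf2 one of 0.09 and an adjusted p = 1.77e-05. Without the block neither passed (adjusted p = 1 for Nrp1, standard error 0.58). In limma with the block but without the mean-variance trend, Nrp1 had an adjusted p = 0.418. The T cell genes Cd4 and Cd3e differed by 0.04 and −0.09, and Il2ra, a chain of the interleukin-2 receptor, by 0.28 (adjusted p = 0.345 in limma with the block). The Foxp3 probe set lay at percentile 18.0 of all probe sets, below the filter, with intensities of 3.82 and 39.1 in Nrp1-negative and 2.11 and 19.98 in Nrp1-positive arrays, so Foxp3 was not tested.

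Nrp1-positive cells had more RNA of the transcription factor genes Ikzf4 and Plagl1, the integrin gene Itgb1 and the interleukin-18 receptor gene Il18r1. They had less RNA of Postn, which encodes the matricellular protein periostin, of the inhibitory receptor gene Lag3, of the immunosuppressive cytokine gene Il10, and of Dapl1, Igfbp4 and Tgfbr3. Itgb1 was 2.02 higher (4.06-fold, standard error 0.23 with the block), Plagl1 1.76, Il18r1 1.58 and Ikzf4 1.13. Postn differed by −2.43, from 514 ± 8.72 to 80.4 ± 6.52 (SD, n = 2), Il10 by −2.00, Lag3 by −1.79, Dapl1 by −1.55, Igfbp4 by −1.32 and Tgfbr3, a coreceptor for TGF-beta, by −1.14. All of these kept one direction in both batches, and Postn was nearly equal in them, at −2.48 and −2.38. Itgb1 was 2.78 in batch 1 and 1.26 in batch 2, and Il18r1 was 2.27 and 0.89. Without Nrp1-negative replicate 1, Il18r1 was 0.76 and Plagl1 1.03, and without Nrp1-negative replicate 2 they were 2.40 and 2.49. Leaving out an array keeps 1 batch only in a group, so such values mix the batch with the group. With Nrp1-negative replicate 1, whose labels conflict, counted as Nrp1-positive, Il18r1 was −0.04, Plagl1 0.20 and Itgb1 0.68.

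In limma with the batch as a block, 107 of 10200 genes were higher and 62 lower in Nrp1-positive cells at an adjusted p below 0.05, and 983 had an unadjusted p below 0.05. Of the 169 genes, 50 differed at least 2-fold, 29 higher and 21 lower, and the median absolute difference was 0.77. The test with the block selects genes with a large mean difference over the batches, which mostly have one direction. The 168 of 169 with one direction in both batches are thus no further evidence. Disagreement between batches weighs little in this test, as most of the variance comes from the prior: Xist passed at −5.40 in batch 1 and 0.08 in batch 2. The groups did not overlap in 134 of the 169, a share that the selection also raises, and in 21.0% of all 10200 genes, where chance gives 33.3%. Limma without the block called 0 genes in either direction, with 142 genes at an unadjusted p below 0.05 and 510 expected by chance. The calls with the block also rest on the mean-variance trend of the variance prior, since without it 0 genes passed, 858 had an unadjusted p below 0.05 and the lowest adjusted p was 0.304. Other settings with the block called between 46 genes, with arrays only scaled to one trimmed mean, and 325, with the mean of a gene's probe sets.

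**Figure D1:**
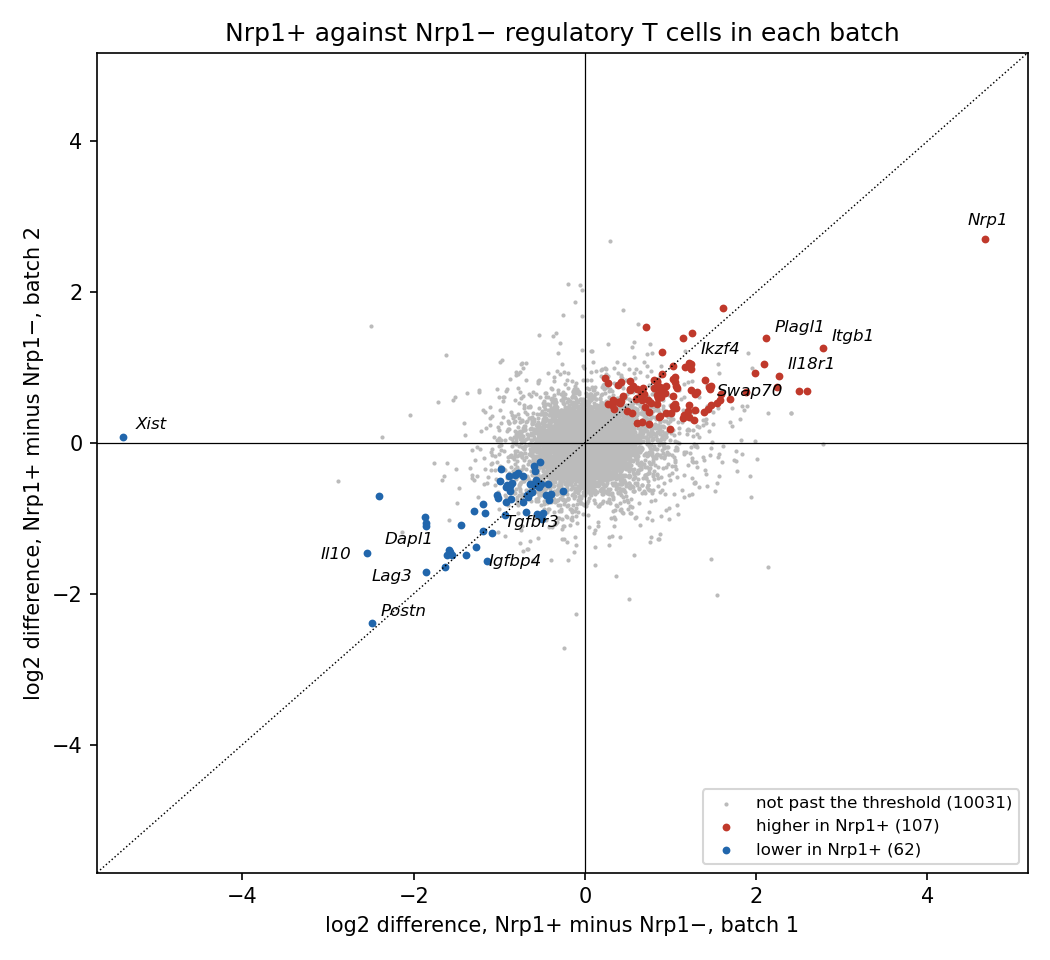
Log2 difference, Nrp1-positive minus Nrp1-negative, in batch 1 (x axis) and batch 2 (y axis) for 10200 genes, each difference taken between 1 array of each group. Red and blue points are the 107 higher and 62 lower genes of limma with the batch as a block, grey points are the other genes, and the dotted line marks equal differences; Nrp1 lies at 4.67 and 2.70 and Xist alone is called with opposite signs, at −5.40 and 0.08.

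No gene passed without the block, so the rule named 10 genes in each direction that did not pass there, and all 20 passed with it. The higher ones were Nrp1, Itgb1, Ikzf4, B3gnt5, Swap70, Ecm1, Kif5c, Hmgn3, D430019H16Rik and Flicr, a long noncoding RNA of the Foxp3 locus. Beside Nrp1 they ranged from 1.02 for Ecm1 to 2.02 for Itgb1, and Ecm1 differed by 1.02 in each batch. The lower ones were Postn, Dapl1, Lag3, Igfbp4, Tgfbr3, Tmie, Slc16a5, Pde5a, Adh1 and Klrb1f, from −1.05 for Klrb1f to −2.43 for Postn. Pde5a, a phosphodiesterase of cyclic GMP, differed by −1.64 in each batch. With the block the rule added Plagl1, Il18r1, 2310015A10Rik, Npas4, Klf12, Niban2, Rad51b and Igsf3 among the higher genes and Il10, Asb2, Ffar2, Dsp, Sccpdh, 4930486L24Rik and Xkrx among the lower. Of these, 2310015A10Rik differed by 1.70, with a range of 0.82 to 2.58 over arrays left out. Npas4, an immediate early transcription factor gene, differed by 1.64 (adjusted p = 0.0478 in limma with the block), at 2.59 in batch 1 and 0.69 in batch 2, and was 0.37 without Nrp1-negative replicate 1, 2.91 without Nrp1-negative replicate 2 and −0.60 with Nrp1-negative replicate 1 counted as Nrp1-positive. Klf12 (1.57) was 0.69, 2.44 and −0.12 in the same order.

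One called gene differed in opposite directions in the batches, and it was looked at after its values were seen. Xist, the noncoding RNA of the inactive X chromosome in female cells, had an intensity of 79.4 in Nrp1-positive replicate 1 against 4100 in Nrp1-negative replicate 1, and of 14682 and 13902 in the Nrp1-positive and Nrp1-negative arrays of batch 2. All 3 Xist probe sets were lower in Nrp1-positive cells in batch 1, by −4.31 to −5.40, and differed by 0.08 to 0.31 in batch 2. The Y-linked genes Eif2s3y, Kdm5d and Uty were present on all arrays. At the probe set that represents each gene, they differed by 0.05 to 0.33 in batch 1 and by −0.18 to 0.10 in batch 2. Other Uty probe sets past the filter differed by 0.49 and −0.12 in batch 1 and by 0.12 and −0.78 in batch 2, in the same order. The sex of the mice is not given in the sources used here, so a difference in sex between the libraries of batch 1 was not separated from the group difference in that batch.

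**Figure D2:**
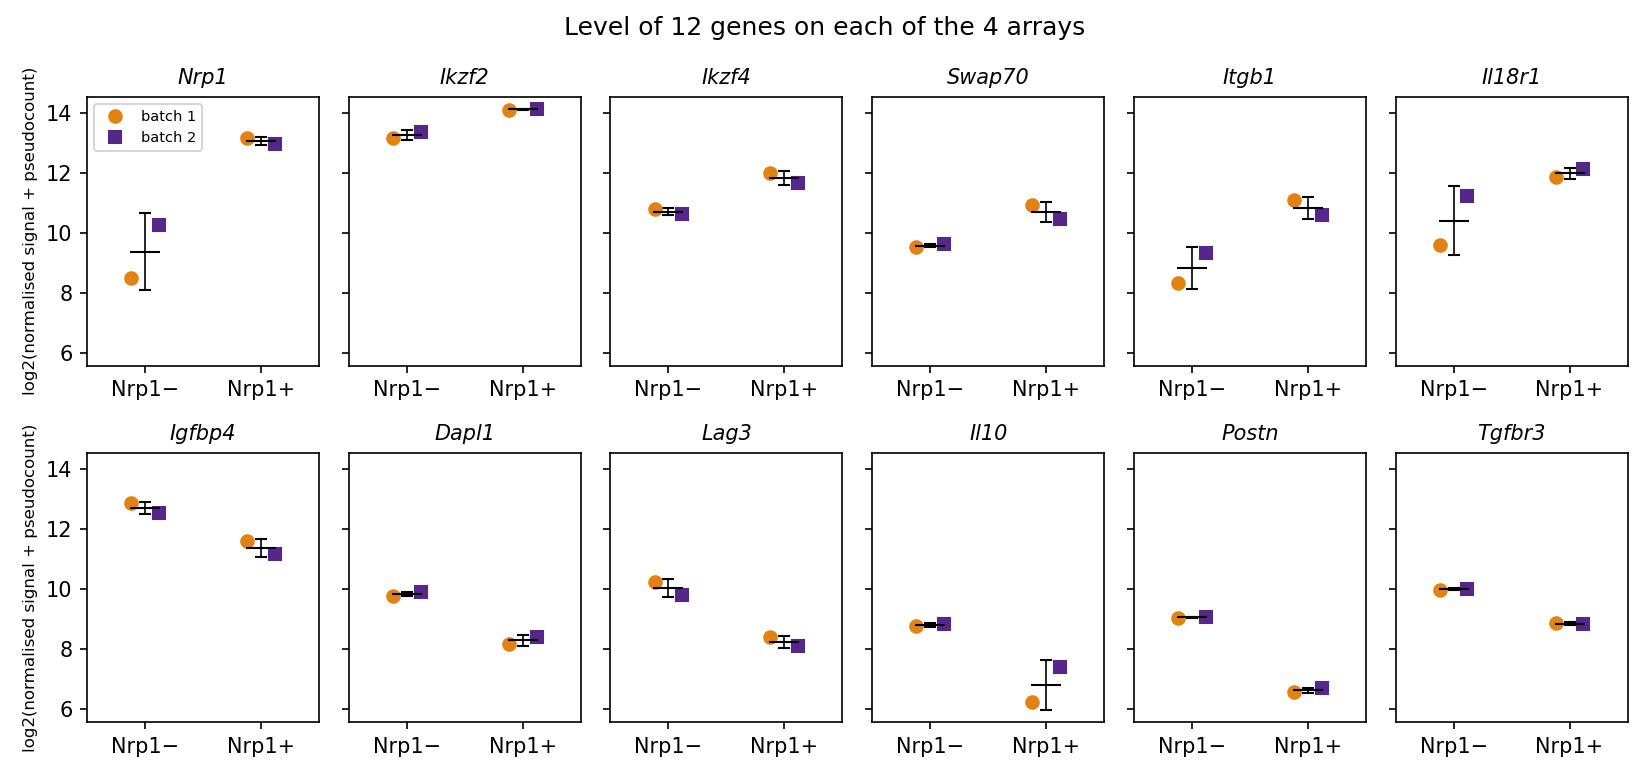
Level of 12 genes, log2(normalised intensity + pseudocount), on each of the 4 arrays, with circles for batch 1, squares for batch 2, and the bar and whiskers for the mean and SD of the 2 arrays of a group. Postn, Dapl1, Lag3, Igfbp4 and Tgfbr3 lie closer within a group than between groups, while Nrp1, Itgb1 and Il18r1 are lower on the Nrp1-negative array of batch 1 than on that of batch 2.

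Of 22 tested genes that mark regulatory T cells, the Treg core list, 7 were higher and 1 lower in Nrp1-positive cells with the block and 14 did not pass, and without the block 0 passed. Camera called the list higher (adjusted p = 2.98e-05, and 5.14e-10 with the block), but the call was lost at adjusted p = 0.750 with an estimated correlation and 0.830 with that and the block, and fry did not call it (0.994, and 0.704 with the block). It was also lost without Nrp1-negative replicate 1 and with that array counted as Nrp1-positive. Both of these fits keep 1 Nrp1-negative array and so mix the batch with the group. Adjusted over the list alone 14 were higher and 2 lower with the block, and 0 passed without it. The higher genes over all genes included Plagl1, the TNF receptor family genes Tnfrsf4 (0.60) and Tnfrsf18 (0.47), Klrg1 (0.76) and S100a4 (0.79), and the lower one was Il10. Klrg1 was 1.03 in batch 1 and 0.49 in batch 2 and S100a4 was 1.27 and 0.30. Without Nrp1-negative replicate 1 they were 0.23 and 0.10, without Nrp1-negative replicate 2 they were 1.28 and 1.48, and with Nrp1-negative replicate 1 counted as Nrp1-positive −0.19 and −0.39. Over arrays left out, Tnfrsf4 ranged from 0.39 to 0.81 and Tnfrsf18 from 0.20 to 0.74. The list median was 0.30, being 0.38 in batch 1 and 0.17 in batch 2. Medians of some lists of other cells took opposite signs in the batches. That of the B cell list was 0.58 in batch 1 and −0.54 in batch 2, and that of the myeloid list 0.36 and −0.27. In the B cell list only Cd74, H2-Aa and H2-Ab1 turned, so its median does not show a change in B cells.

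Of 5 genes known to be higher in thymus-derived regulatory T cells, Ikzf2 and Swap70 (1.12) were higher in Nrp1-positive cells with the block and 3 did not pass, and both genes known to be lower in them, Dapl1 and Igfbp4, were lower. Camera called the first list higher (adjusted p = 3.39e-07, and 1.68e-09 with the block) and the second lower (3.74e-09, and 8.68e-11 with the block), and both calls were lost at adjusted p = 0.430 with an estimated correlation and 0.830 with that and the block. These 2 lists come from general knowledge of the field, and a paper may have chosen some of their genes on these samples, so they are not independent evidence. Without the block 0 genes of either list passed over all genes. Adjusted over the list alone, 4 of the 5 were higher with the block, with Gpr83 at 0.32 and Nt5e at 0.28, and 2, Ikzf2 and Swap70, without it. Over arrays left out, Gpr83 ranged from −0.06 (without Nrp1-negative replicate 2) to 0.70 and Nt5e from −0.0037 (without Nrp1-positive replicate 1) to 0.57. The median of this list was 0.32, at 0.55 in batch 1 and 0.47 in batch 2, and fry did not call it (adjusted p = 0.597, and 0.603 with the block). Dapl1 and Igfbp4 passed adjusted over the list alone in either test, and their median was −1.44, at −1.44 in batch 1 and −1.43 in batch 2. Theirs was the list that fry called (adjusted p = 0.0126, and 0.0350 with the block), and camera gave it an adjusted p = 0.141 with Nrp1-negative replicate 1 counted as Nrp1-positive.

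Most naive and central T cell genes did not pass, and those that did went both ways. Of 16 tested, 5 were lower with the block (Igfbp4 and Dapl1, which are also on the list above, Ccr7 at −0.49, Actn1 at −0.45 and Satb1 at −0.39), 2 were higher and 9 did not pass. The higher ones were Id3 (0.65), an inhibitor of E-protein transcription factors, and Il7r (0.46), a chain of the interleukin-7 receptor, which ranged from 0.20 to 0.72 over arrays left out. Adjusted over the list alone, 6 were lower and 3 higher with the block, and Igfbp4 and Dapl1 lower and Id3 higher without it, where 0 passed over all genes. The list median was −0.22, at −0.22 in batch 1 and −0.10 in batch 2. Camera called the list lower (adjusted p = 0.00860, and 0.00599 with the block), and lost the call at adjusted p = 0.974 with an estimated correlation and 0.830 with that and the block. Without Nrp1-negative replicate 1 the direction turned, and without Nrp1-positive replicate 2 the call was lost, in fits that mix the batch with the group.

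Most effector Treg genes did not pass, and the list was not called with all 4 arrays in the groups of their titles. Of 19 tested, Lag3, Il10 and Maf (−0.53) were lower with the block, Itgb1 and Klrg1 were higher and 14 did not pass, and adjusted over the list alone 5 were lower and 3 higher. Maf was −0.19 without Nrp1-negative replicate 2 and −0.88 without Nrp1-negative replicate 1. Without the block 0 passed over all genes, and Lag3, Il10 and Itgb1 passed adjusted over the list alone. The list's median was 0.05 and its mean −0.08, with a camera adjusted p of 0.727 (lower), and 0.729 with the block, and a fry adjusted p of 0.994, and 0.728 with the block. Camera called the list lower without Nrp1-negative replicate 1 or Nrp1-positive replicate 2 and higher without Nrp1-negative replicate 2. These fits keep 1 batch only in a group, and the list was 0.62 higher in batch 2 (median). Among 15 homing receptor genes, the integrin gene Itgb8 was higher (1.08) and the chemokine receptor gene Cxcr5 lower (−0.68) with the block, 13 did not pass, and adjusted over the list alone 2 were higher and 1 lower (camera adjusted p = 0.630, and 0.397 with the block). Itgb8 was 0.54 without Nrp1-negative replicate 1, 1.61 without Nrp1-negative replicate 2 and 0.0081 with Nrp1-negative replicate 1 counted as Nrp1-positive. Rora (0.65) was the member of 7 T helper lineage genes that was higher with the block, also adjusted over the list alone (camera adjusted p = 0.450, and 0.397 with the block), with a range of 0.38 to 0.93 over arrays left out. Cxcr5 was likewise the called member of 9 follicular helper genes by either adjustment (camera adjusted p = 0.829, and 0.597 with the block). In the TGF-beta pathway list, with 16 genes tested, Tgfbr3 was lower and Itgb8 and Tgif1 (0.65) higher with the block and 13 did not pass. Tgif1 was 0.22 without Nrp1-negative replicate 1, 1.08 without Nrp1-negative replicate 2 and −0.13 with Nrp1-negative replicate 1 counted as Nrp1-positive. Adjusted over the list alone, 4 of its genes were higher and 1 lower, and without the block Tgfbr3 passed (camera adjusted p = 0.447, and 0.199 with the block).

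Few proliferation genes passed, and the direction of the list turned where leaving out an array mixed the batch with the group. Of 29 tested, 28 had a negative difference over all 4 arrays, and Stmn1 (−0.58), Ube2c (−0.69) and Birc5 (−0.65) were lower with the block while 26 did not pass. Adjusted over the list alone 6 were lower, with Aurkb at −0.97, Mcm2 at −0.42 and Rrm2 at −0.41, and without the block 0 passed by either adjustment. The list median was −0.26, at −0.12 in batch 1 and −0.50 in batch 2. Camera called the list lower (adjusted p = 0.0498, and 1.68e-09 with the block), but lost the call at adjusted p = 0.974 with an estimated correlation, 0.830 with that and the block, and 0.166 with a stricter filter. Without Nrp1-negative replicate 2 or Nrp1-positive replicate 1 camera called the list higher. Leaving out either of these arrays spreads the batches unevenly over the groups. The list was 2.38 higher in batch 2 (median), so the batch alone could turn it. Over arrays left out, Stmn1 ranged from −1.93 to 0.77, Ube2c from −2.51 to 1.14, Birc5 from −2.03 to 0.72, Aurkb from −2.60 to 0.66 and Rrm2 from −1.64 to 0.83, each above 0 without either of these arrays, and Mcm2 ranged from −0.54 to −0.30.

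Lists of T cell signalling and metabolism did not pass in camera with all 4 arrays in the groups of their titles. Camera called the TCR-induced and immediate early list higher without Nrp1-negative replicate 1 or Nrp1-positive replicate 2. It called the heat shock and stress list with each array left out in turn, in directions that differed. These fits keep 1 batch only in a group, and batch 2 minus batch 1 medians were −0.35 and −0.36 for these lists. With the block 0 members of the signalling and metabolism lists passed over all genes or adjusted over the list alone, and likewise without it. The medians were 0.08 for 20 TCR-induced and immediate early genes (camera adjusted p = 0.447, and 0.25 with the block), −0.04 for 16 type I interferon genes (0.761 and 0.729), 0.05 for 12 semaphorin, plexin and VEGF genes (0.778 and 0.662), −0.07 for 12 glycolysis genes (0.727 and 0.662) and −0.05 for 13 heat shock and stress genes (0.898 and 0.955). The heat shock list had a negative median but a higher direction in camera with the block. Fry called the TCR-induced list for change in either direction with the block (adjusted p = 0.0401).

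Markers of other blood cells did not follow the Nrp1 sort in a common direction, and with the block 0 of their genes passed over all genes. The medians of batch 1 and batch 2 were 0.58 and −0.54 for 6 B cell genes, 0.27 and −0.16 for 7 plasmacytoid dendritic cell genes, 0.36 and −0.27 for 14 myeloid genes, and −0.0013 and −0.56 for 8 CD8 T and NK cell genes. Camera adjusted p values were 0.996, 0.996, 0.970 and 0.450 in that order, and 0.740, 0.868, 0.708 and 0.461 with the block. Camera called the B cell, myeloid and CD8 T and NK lists lower without Nrp1-negative replicate 1 and higher without Nrp1-negative replicate 2. These fits keep 1 batch only in the Nrp1-negative group. The medians of these lists were 0.82, 1.91 and 0.83 higher in batch 2, so the batch alone could turn them. The plasmacytoid list had a median of 0.03, a mean of −0.03 and a higher direction in camera, but a lower one with the block. The brightest B cell genes were Ighm (−0.20) and H2-Aa, which differed by 0.75 in batch 1 and −0.92 in batch 2. S100a8 (0.06) and S100a9 (−0.03), calcium-binding proteins of neutrophils and monocytes, led the myeloid list, Ccr9 (−0.20) and Irf8 (0.08) the plasmacytoid list, and Ccl5 (−0.39) and Gzma (−0.48) the CD8 T and NK list, where Nkg7 (0.75) was higher adjusted over the list alone with the block. Nkg7 was 1.48 in batch 1 and 0.0098 in batch 2, and was −0.24 without Nrp1-negative replicate 1, 1.73 without Nrp1-negative replicate 2 and −0.82 with Nrp1-negative replicate 1 counted as Nrp1-positive. The erythroid list, with 3 genes tested, was lower in Nrp1-positive cells (camera adjusted p = 0.0328, and 0.0227 with the block), with a median of −0.13 in batch 1 and −1.44 in batch 2. That call was lost at adjusted p = 0.974 with an estimated correlation, 0.930 with that and the block, and without Nrp1-negative replicate 2 (0.959), Nrp1-positive replicate 1 (0.110) or Nrp1-positive replicate 2 (0.0579). Its brightest genes were Car2 (−0.78), lower adjusted over the list alone with the block but 0.06 without Nrp1-negative replicate 2, and Slc4a1 (−0.53). The other member, Klf1, was at 0.52 in batch 1 and −2.08 in batch 2. Slc4a1 and Klf1 were dim, with mean log2 levels of 6.73 and 6.66, near the filter level of 6.43.

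**Figure D3:**
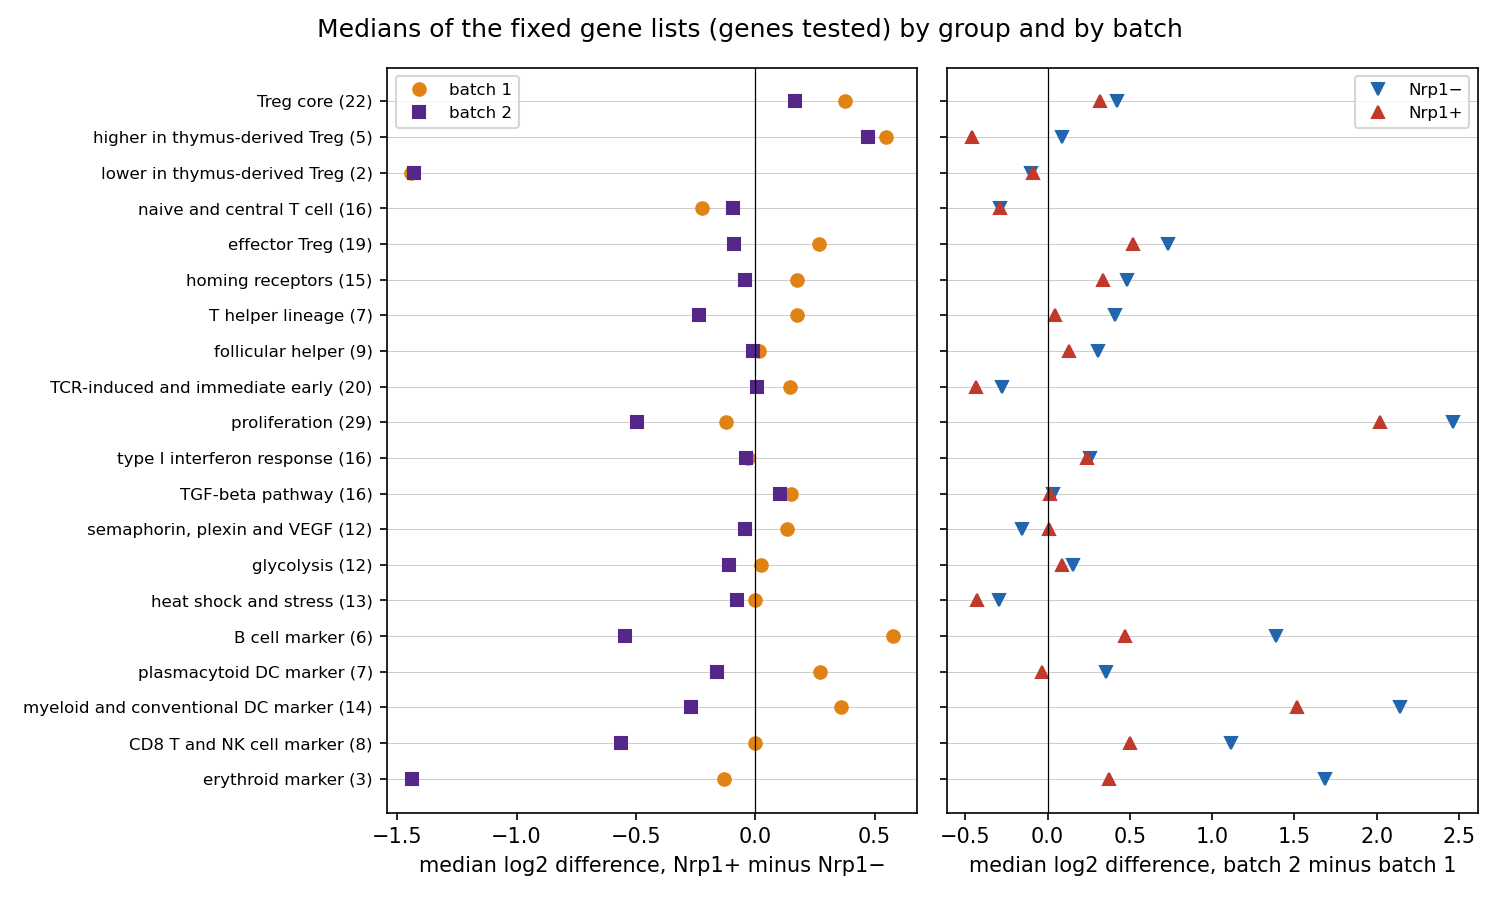
Median log2 difference of each of the 20 fixed gene lists, with the number of genes tested in brackets: on the left Nrp1-positive minus Nrp1-negative in batch 1 (circles) and batch 2 (squares), on the right batch 2 minus batch 1 within Nrp1-negative (downward triangles) and Nrp1-positive cells (upward triangles). Dapl1 and Igfbp4, the lower thymus-derived list, sit at −1.44 and −1.43 on the left, and the proliferation and myeloid lists are the farthest to the right between batches.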

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

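The tests of myeloid cell share, of a lower share of sorted cells and of conventional T cells were chosen only after the results they address were seen. The spiked poly-A control transcripts, which enter no comparison, gave a median scaled intensity over 12 probe sets of 2768.83 on Nrp1-negative replicate 1 and 2383.51 on Nrp1-positive replicate 1, against 4.61 and 6.38 on the batch 2 arrays.

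The Nrp1 difference was 4.67 in batch 1 and 2.70 in batch 2. Carry-over of Nrp1-positive cells into the Nrp1-negative library of batch 2 could give this with 11.9% carried-over cells, which predicts a mean shift of −0.147 over the 50 other bright genes most higher in Nrp1-positive cells. The measured mean, batch 2 minus batch 1, was −0.28 (95% bootstrap interval −0.397 to −0.155), with 40 of 50 smaller in batch 2. The interval ends just below the predicted value. That prediction rests on 1 of the 4 Nrp1 probe sets, and the interval resamples genes rather than arrays, so carry-over is left open. A narrower range of all differences in batch 2 could also give the smaller Nrp1 difference. Over the 50 genes most lower the mean shift was −0.0592 (interval −0.33 to 0.13), which leaves this open. These cannot be told apart with 1 pair of arrays per batch, and no biological explanation was tested.

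Myeloid markers were higher in batch 2 in both groups, with a median over 14 genes of 1.91, and S100a8 had intensities of 6008 and 6913 in batch 1 against 25057 and 23809 in batch 2. The quantile step does not account for it, since with arrays only scaled to one trimmed mean the median was 1.72. The authors' own processing and the labelling, which split as the batches do, were not tested. A lower share of sorted cells, with every other cell type raised alike, would raise the lists of other cells equally only for genes that sorted cells lack. The other lists rose less, but which of their genes sorted cells express was not tested, so this cannot decide. Cd4 had intensities of 2204 and 2272 in batch 1 and 729 and 746 in batch 2, Nrp1-negative array first. Cd3e had 7815 and 7663, then 5906 and 5317. The Treg core median instead rose by 0.52, so a lower share stays open. Against a lower quartile of 1.46 for the myeloid list, the CD8 T and NK list had a median of 0.83 and an upper quartile of 1.02. The plasmacytoid dendritic cell list had 0.15 and 0.34, but some of its genes, such as Cox6a2 (6.78), lay near the filter level, where a rise could be hidden. B cell and erythroid medians were 0.82 and 0.69, so an unequal rise of other cell types stays open. More myeloid cells or their RNA in both batch 2 libraries is consistent with a median of 1.51 in the group with the smaller rise and 2.14 in the other, although the CD4 and Foxp3 gates would remove such cells. No biological explanation was tested.

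Of 22 Treg core genes 7 were higher and 1 lower in Nrp1-positive cells with the block and 0 without it, and the call of the list as higher was lost with an estimated correlation (adjusted p = 0.750, and 0.830 with the block). Foxp3-negative conventional T cells in the Nrp1-negative libraries, which the Foxp3 gate would remove, could give this, and would lower all Treg-restricted transcripts by about the 0.76 median of the called Treg core genes. The median of Il2ra, Ctla4, Izumo1r and Gpr83 was 0.27 (pooled standard error 0.10), with a range from −0.09 to 0.32. The 0.76 comes from the 7 genes that passed as higher in these data, a choice that raises it. The median of all 22 was 0.30, near 0.27, so this comparison cannot decide. Il7r, predicted to be higher in Nrp1-negative libraries with such cells, was higher in Nrp1-positive cells by 0.49 and 0.43 in the batches, but is 1 gene. Conventional T cells stay open as a cause, as does a difference between the sorted populations themselves, which was not tested apart from them.

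The batch block gave 169 genes in the real grouping, and exchanging the groups in batch 2 gave 0, with 238 at an unadjusted p below 0.05, so 1 of the 2 splits reached the real value. The splits are too few for a share under 0.05.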

How the results depend on the processing

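The fits that join the batch block to another setting, scaling to one trimmed mean, and the block with an estimated correlation or fry were chosen after seeing the data. Without the block, limma called 0 genes in either direction under each alternative, except 1 higher without Nrp1-negative replicate 2 (0 to 1 higher and 0 to 0 lower over arrays left out). The replicate block gave 107 higher and 62 lower genes, and took Nrp1 (3.68) and Ikzf2 (0.85) past the threshold. The labels do not say that equal numbers share mice, and with 2 pairs the deviations of same-numbered arrays correlated at 0.72 across genes. With the block, higher and lower counts were 188 and 108 with the median as pseudocount, 50 and 28 above percentile 75 of probe sets, where fewer genes are tested, 38 and 28 as deposited, 29 and 17 scaled to one trimmed mean, 67 and 54 with median centring, 211 and 114 with the mean of a gene's probe sets, and 0 and 0 without the variance trend. The 169 genes kept their direction in each of these fits that tested them. No array could be left out with the block, since no residual degrees of freedom remain. Of 981 values of 63 named genes under the alternatives, 24 changed sign, in 18 genes, each time with an array left out or moved to the other group. Leaving out an array moved 30 of the 63 by over 1.5 times: 27 and 20 for Nrp1-negative replicates 1 and 2, and 15 and 17 for Nrp1-positive replicates 1 and 2. Signal over background limits dim probe sets such as that of Foxp3, which was below the filter. The cells were sorted on Foxp3, so its low signal cannot be read as low Foxp3 RNA.

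Camera called 6 lists, 4 to 6 under other settings of the values, 7 to 12 with an array left out, 10 with Nrp1-negative replicate 1 counted as Nrp1-positive, 0 with an estimated correlation and 1 with fry, both with and without the block. The cause was not tested for any of the following values, which are adjusted p. With an estimated correlation they were 0.750 for Treg core, 0.430 for both thymus-derived lists, and 0.974 for naive, proliferation and erythroid genes; with the block added, 0.830, and 0.930 for erythroid genes. With fry they were 0.597 for the higher thymus-derived list and 0.994 for Treg core, naive, proliferation and erythroid genes, and with the block 0.704 for Treg core and proliferation, 0.603 for the higher thymus-derived list and naive genes, and 0.728 for erythroid genes. With Nrp1-negative replicate 1 counted as Nrp1-positive, Treg core had 0.919 and the lower thymus-derived list 0.141, and the direction turned for naive (0.0830), homing (0.0237), heat shock (0.0190) and myeloid genes (1.62e-06). Proliferation missed the threshold with the smaller pseudocount (0.0517), no filter (0.119), percentile 75 (0.166), median centring (0.0943) and the mean of probe sets (0.0508), and the erythroid list had no value at percentile 75. Over arrays left out, the range was 1.86e-07 to 0.0789 for Treg core, 1.40e-07 to 0.00170 and 4.94e-08 to 6.11e-06 for the higher and lower thymus-derived lists, 1.20e-05 to 0.867 for naive, 1.11e-18 to 0.000359 for proliferation and 1.67e-05 to 0.959 for erythroid genes. It was 0.000386 to 0.296 for effector Treg and for B cell genes, 0.00170 to 0.0411 for heat shock, 1.15e-07 to 0.00177 for myeloid, 8.35e-05 to 0.882 for CD8 T and NK genes, 0.00222 to 0.651 for TCR-induced, 0.00266 to 0.754 for homing and 0.0326 to 0.675 for T helper genes, past the threshold without Nrp1-negative replicate 2 for homing and T helper genes. The direction turned without Nrp1-negative replicate 1 for naive, heat shock and myeloid genes, without Nrp1-negative replicate 2 for effector Treg, proliferation, B cell and CD8 T and NK genes, without Nrp1-positive replicate 1 for proliferation, and without Nrp1-positive replicate 2 for heat shock and myeloid genes; leaving out 1 array spreads the batches unevenly over the groups.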

Other observations

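Gene lists also differed between the batches, a comparison chosen after the data were seen, on the lists fixed before. With limma and group as the other term, 1602 genes were higher and 1363 lower in batch 2 than in batch 1. Of all 10200 genes, whether they passed or not, 652 differed at least 2-fold. Proliferation genes stood highest: 27 of 29 were higher in batch 2, with a median of 2.38 (5.19-fold). Of 14 myeloid genes 13 were higher, and S100a8, S100a9, Lyz1 and Lyz2 were among the brightest. Effector Treg genes were higher in 12 of 19 (median 0.62) and Treg core genes in 12 of 22 (median 0.52, with 5 lower), while 8 of 16 naive and central T cell genes were lower and none higher (median −0.28). Among TCR-induced and immediate early genes 9 of 20 were lower and 3 higher (median −0.35), and among heat shock and stress genes 8 of 13 were lower and 1 higher (median −0.36). The batch and the authors' scaling are the same split here, so these differences cannot be assigned to the cells.

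Xist was near the level of the filter (6.43 on the log2 scale) on Nrp1-positive replicate 1 alone, at 6.61 against 12.01, 13.76 and 13.84 on Nrp1-negative replicate 1, Nrp1-negative replicate 2 and Nrp1-positive replicate 2. Eif2s3y lay between 11.07 and 11.45 on all 4 arrays. Among 3682 unnamed probe sets, 14 passed with the batch as a block in limma over all probe sets, 10 higher and 4 lower in Nrp1-positive cells.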
